A study of Mus musculus with 2 samples.

How the data were processed

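The 2 libraries were made by Drop-seq from microdissected posterior second heart field and heart tube of wild-type CD1 mouse embryos at E10.0, with about 80 embryos pooled for each library on a separate day, per the labels' protocols. Per the labels, the libraries are biological replicates of 1 group. The deposited values were whole-number UMI counts per gene and cell barcode, with no normalization applied by the authors as far as the values show, and the submitters' processing notes name the genome build mm10 and Scanpy without versions. The aligner, the counting tool and the rule for selecting barcodes are not given in the sources used here. The files hold 52550 gene identifiers, of which 99.7% were found in GENCODE M21 without the version suffix and 93.3% with it, so the annotation used by the authors may be another release. Coordinates and strands of the 165 genes located come from that release on GRCm38 (mm10), and 33 of them overlap another gene on the same strand. Where 1 of the 91 symbols carried by several identifiers is named, it stands for the identifier with the most UMIs.

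Replicate 1 held 5000 barcodes with 11958912 UMIs and replicate 2 held 7497 with 14131384 UMIs, of which 43 and 3 barcodes had 0 UMIs. The libraries shared 82 barcodes, and their gene totals differed by far more than counting error (chi-square over degrees of freedom 22.96 over 18991 genes), so they are not 1 library entered again. Cells with at least 400 genes and at most 10% mitochondrial UMIs passed, 4038 and 4934. Scrublet was run per library with an expected rate of 6%, and its automatic threshold marked 0 and 2 cells. Since that was under 0.5%, the rule set beforehand removed the cells with the highest 5% of scores, with cells tied at that limit kept, which took out 156 and 217 cells and left 3882 and 4717 cells with 11240488 and 12776544 UMIs.

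Genes were divided so that no tested gene helped define a class. The 25984 clustering genes were the cell type markers and a seeded random share of the other genes, without mitochondrial, ribosomal protein, haemoglobin, Xist and Y-linked genes, and without the members of the fixed gene lists. The 26566 held-out genes alone were tested. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were scaled within each library, reduced to 30 principal components and clustered with 20 neighbours and Leiden resolution 1. A cluster took the name of a cell type when at least 3 of its markers were raised at least 2-fold and detected in at least 5% of its cells, and the suffix "-like" marks that names rest on markers alone. Of 15 clusters, 13 were named and formed 12 classes.

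UMI counts were summed per library and class, which gave 24 sums. They were tested with edgeR's quasi-likelihood F test (two-sided, TMM scaling, filterByExpr) in a model of class and library, with 11 residual degrees of freedom and Benjamini-Hochberg adjustment. Classes within a library share its embryos and day, and library deviations from the class means correlated between classes by 0.424 to 0.807 across 1874 genes, which is why the library entered as a block. The p-values rest on how far class differences varied between only 2 libraries, pooled over 12 classes. They leave out the shift between libraries that the block removed. The classes were defined from the same cells, so the p-values describe differences between classes and not between groups of animals. The contrast of a class with the others is against the mean of their log levels. Gene lists were tested with camera from limma (preset correlation 0.01, and estimated), and with fry beside it, adjusted over 18 lists, or over lists and classes together. The score between SHF progenitor-like and cardiomyocyte-like cells was the projection on the line between their centroids, in 6 bins of equal width merged to 4 where a bin held under 20 cells in a library. It was tested for a linear trend and, one-sided with a Bonferroni correction over the middle bins, for a middle bin above both ends.

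CPM values are means of 2 libraries with their SD. A fold against a class with 0 UMIs was computed against a floor of 3 counts per library, which was 4.04 CPM in cardiomyocyte-like and 1.81 CPM in SHF progenitor-like cells on average. For 1 to 3 UMIs the ratio is given with an exact 95% interval for counting error only. Shares of cells carry exact 95% binomial intervals.

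The comparisons, the lists, the markers, the alternatives and the rule for named genes were fixed before the data were examined. Named genes were the 12 largest log2 fold changes in each direction among genes with an adjusted p under 0.05, the same direction in both libraries and at least 50 CPM in the higher class, without list members and unnamed models. All measured members of the Hedgehog and heterochronic lists were named, the 4 members with the smallest adjusted p of each other list, the 4 largest changes per class, and up to 8 genes of the middle bins. In data simulated from the fitted levels and spread, the contrast of SHF progenitor-like and cardiomyocyte-like cells recovered 49% of genes changed 2-fold and 80% of genes changed 4-fold, and 5.1% of its calls were false. The trend along the score recovered 74% and 98% with 2.3% false calls, and the test for the middle bins 60% and 100% with 0 false calls. Each simulation changed 200 genes, with the other genes level between the classes or bins compared and the classes taken as given. For the middle bins the changed genes were raised in both middle bins together, so peaks in 1 bin and genes trending along the score were not simulated. These rates need not hold for the data, where more genes differed. In the first of these simulations, where changed genes were drawn at random and not by list, camera called 0 of 18 lists. Its genes were drawn independently, so it cannot show false calls that correlated genes would bring.

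Alternatives changed the scaling, the test, the low-count filter, the classes in the fit, the block, the cell filters, doublet removal, cluster resolution, library scaling, the genes used for clustering, the depth of the cells, the number of bins and the set test. The comparison of atrial-like and ventricular-like cells and its alternatives were not run, since only 1 cluster of cardiomyocyte-like cells was found. Unnamed clusters entered no comparison. The planned comparison of progenitors with and without a UMI of a Hedgehog target, and some genes that the naming rule chose, are not reported here. The analysis used Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2, pandas 2.3.3, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.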

Results

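Single-cell expression was measured by Drop-seq, in which a cell and a barcoded bead share a droplet and each captured mRNA molecule is counted once through its unique molecular identifier (UMI). The tissue was the microdissected posterior second heart field (SHF), a field of mesodermal progenitors behind the heart, together with the heart tube to which its cells contribute, from wild-type CD1 mouse embryos at E10.0. About 80 embryos were pooled for each of the 2 libraries, which were biological replicates of 1 group processed on different days. Replicate 1 held 5000 barcodes and 11958912 UMIs, and replicate 2 held 7497 barcodes and 14131384 UMIs. After filtering and removal of cells with high doublet scores, 3882 and 4717 cells remained, with medians of 1380.5 and 1500.0 UMIs per cell. No treated or mutant group was analysed here, so the comparisons are between cell classes within the same libraries, and each value comes with its SD over the 2 libraries (n = 2) where an SD is given.

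With the settings fixed beforehand the tissue resolved into 12 named cell classes. The most abundant there were pharyngeal or limb mesenchyme-like cells, at 12.9% ± 0.096 of kept cells (SD, n = 2), and SHF progenitor-like cells, at 10.8% ± 1.24 (SD, n = 2), which were named from raised Isl1, Osr1 and Aldh1a2. Foregut endoderm-like cells made up 9.32% ± 2.32, neural crest or glia-like cells 6.83% ± 1.25, epicardial-like cells 5.82% ± 0.651 and cardiomyocyte-like cells 4.66% ± 0.249. Endocardial or endothelial-like (4.44%), neural tube-like (4.10%), erythroid-like (3.68%), surface ectoderm-like (3.16%), paraxial mesoderm-like (3.13%) and hepatoblast-like cells (2.44%) formed the rest. The classes depended on the settings. Of 8 alternatives for the cell filters, doublet removal, scaling, resolution and the genes or counts used for clustering, surface ectoderm-like cells were named in 1 (doublets kept), and pharyngeal or limb mesenchyme-like and paraxial mesoderm-like cells in 5 each. In its 5 the mesenchyme-like class had a lower mean share than foregut endoderm-like cells. It made up 5.20% at resolution 1.6 and 8.87% with at least 800 genes per cell. In the latter SHF progenitor-like cells made up 17.0% and foregut endoderm-like cells 16.3%. In replicate 1 alone the mesenchyme-like share was the higher with no mitochondrial filter (10.8% against 10.2%). The same held there with genes scaled over both libraries together (10.6% against 10.1%). Across these 8 alternatives epicardial-like cells made up 3.70% (counts split into a clustering and a testing share) to 8.0% (at least 800 genes per cell). Neural crest or glia-like cells made up 4.32% (another random share of the genes) to 9.22% (split counts). Unnamed cells made up 17.0% (at least 800 genes per cell) to 46.5% (resolution 0.6). The endocardial or endothelial-like cluster was also led by the blood-cell genes Pf4 and Lyz2. A further 28.7% ± 1.58 of cells lay in 2 clusters that stayed unnamed, numbered 1 and 10, whose joint median depth was 739 and 799.5 UMIs in replicates 1 and 2. Foregut endoderm-like cells took 7.68% of replicate 1 (exact 95% binomial interval 6.86% to 8.56%) and 10.96% of replicate 2 (10.1% to 11.9%). The cardiomyocyte-like cells fell in 1 cluster that carried raised atrial markers (Stard10, Angpt1, Myl1, Cav1) and raised ventricular markers (Myl2, Lbh), so atrial-like and ventricular-like cells could not be named separately.

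The first comparison asked how progenitors of the field differ from the cardiomyocytes of the heart tube, the subject of a series about Hedgehog-dependent networks in cardiac progenitors. SHF progenitor-like cells carried higher levels of Hedgehog targets, of RNA regulators known for timing development, of patterning transcription factors and of cell cycle genes. Cardiomyocyte-like cells carried higher levels of cardiac transcription factors, of sarcomere genes and of genes of oxidative phosphorylation. Of 5857 held-out genes tested, which took no part in defining the classes, 796 were higher in SHF progenitor-like cells and 822 were higher in cardiomyocyte-like cells at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg). Among these, 272 and 493 differed by more than 2-fold.

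Genes of transcription factors and chemokines were among the 12 largest differences towards SHF progenitor-like cells, with list members left out. Nkx6-1, a homeodomain transcription factor on chromosome 5 from 101658139 to 101664996 (GRCm38, minus strand), reached 94.1 ± 11.01 CPM in SHF progenitor-like cells and had 0 UMIs in cardiomyocyte-like cells, which makes it at least 23.3-fold higher against a floor of 3 counts per library. The chemokine gene Cxcl13 stood at 197 ± 21.4 CPM against 3 UMIs in all cardiomyocyte-like cells, a ratio of 98.4 (exact 95% counting interval 33.5 to 478). The long non-coding RNA Fendrr, which lies next to Foxf1 on chromosome 8, gave a ratio of 38.9 (10.6 to 324) from 176 and 2 UMIs. Ifitm1 was 18.4-fold higher, Barx1, a stomach mesenchyme transcription factor, 13.4-fold, and Sparcl1 8.51-fold. Ypel1 (4.72-fold), Hoxa5 (4.09-fold), Sox11 (3.93-fold), Psat1 of serine synthesis (3.77-fold), Hsd11b2 (3.43-fold) and the chemokine gene Cxcl12 (3.39-fold) completed the 12 largest differences. Adjusted p-values of the 12 genes were 1.97e-06 or smaller (edgeR quasi-likelihood, Benjamini-Hochberg), and each was higher in both libraries, as the naming rule required.

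Muscle genes were among the 12 largest differences in the other direction, with list members left out. Cox6a2, the muscle form of a cytochrome c oxidase subunit, reached 136 ± 7.21 CPM in cardiomyocyte-like cells and the calcium-binding protein gene Pvalb 55.3 ± 19.0 CPM. Neither had a UMI in SHF progenitor-like cells, so they were at least 75.4-fold and at least 30.6-fold higher. The small heat shock protein gene Hspb2 had 331 UMIs against 1, a ratio of 749 (134 to 29700), and the calcium store gene Casq1 had 269 against 3, a ratio of 203 (68.7 to 990). Trdn (244, interval 43.0 to 9740), Hspb3 (201, 35.2 to 8050), Pnmt (186, 32.4 to 7420) and Nppb (123, 33.3 to 1030) also rested on 1 or 2 UMIs in SHF progenitor-like cells. Hspb1 was 164.0-fold and Ppp1r14c 136-fold higher. Acta1 (131-fold) and Acta2 (3922 ± 1644 CPM against 33.5 ± 27.9) are related to the abundant cardiac actin gene, and Hspb2 overlaps Cryab on the other strand. These counts are uncertain where the counting could not separate such genes, which was not tested.

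All 6 measured members of the Hedgehog target list were higher in SHF progenitor-like cells, over all genes and adjusted over the list alone. Foxf1, a forkhead transcription factor gene (ENSMUSG00000042812.5) at 121084386 to 121088144 on chromosome 8 (plus strand), stood at 112 ± 12.2 CPM against 4.04 ± 0.209, a log2 fold change of 4.66 ± 0.41 (SE; adjusted p = 1.17e-13, edgeR quasi-likelihood with Benjamini-Hochberg). Hhip, which encodes a Hedgehog-binding inhibitor (chromosome 8, 79965851 to 80058006), stood at 52.1 ± 12.6 against 4.69 ± 0.709 CPM, a log2 fold change of 3.34 ± 0.50. Gli1, the transcriptional effector (ENSMUSG00000025407.7, chromosome 10, 127329882 to 127341974), stood at 42.1 ± 6.27 against 7.43 ± 1.33 CPM, and Ptch1, the receptor (chromosome 13, 63508328 to 63573598), at 93.7 ± 19.9 against 27.9 ± 11.9 CPM. Their log2 fold changes were 2.40 ± 0.42 and 1.67 ± 0.28. Foxc2 was 4.01-fold higher, with a log2 fold change of 0.99 without replicate 2 and 3.25 without replicate 1, and Foxl1 had 71 UMIs against 3, a ratio of 10.5 (3.44 to 51.9). Foxf1, Foxl1 and Foxc2 share their strand with the read-through model Gm20388. The list's median log2 fold change was 2.81 (camera adjusted p = 5.26e-06 with a preset correlation, adjusted p = 0.00259 with an estimated correlation).

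Of the 13 measured genes of Hedgehog transduction, Gli3 (log2 fold change 1.38 ± 0.33) and Smo (0.97 ± 0.28) were higher in SHF progenitor-like cells and 11 did not pass, with the same 2 adjusted over the list alone and a camera adjusted p of 0.119 (fry, also higher there, adjusted p = 0.000696). Among the values that did not pass, Ift88 stood at 36.7 ± 22.4 against 20.9 ± 3.93 CPM, Evc2 at 19.4 ± 4.11 against 8.77 ± 1.40, Kif3a at 80.9 ± 9.44 against 96.9 ± 30.7, Gas1 at 49.9 ± 2.90 against 44.3 ± 3.42 and Arl13b at 34.7 ± 10.9 against 36.5 ± 9.50. Evc, Lrp2, Boc, Gli2, Cdon and Sufu had 17.0 CPM or less in both classes. Of 4 measured genes of ligands and release, Scube3 was higher in SHF progenitor-like cells (14.4 ± 2.20 against 3.34 ± 0.778 CPM), Scube1 did not pass (17.2 ± 3.32 against 9.38 ± 1.42), and Scube2 had 0 UMIs against 2. Shh passed (adjusted p = 0.0332, edgeR quasi-likelihood), but its 19 UMIs all came from replicate 2, with 0 in replicate 1 and 0 in cardiomyocyte-like cells, which makes it at least 1.59-fold higher. Barcodes of replicate 2 with 10 to 200 UMIs, taken here as mostly free RNA, held 2 UMIs of Shh (36.0 CPM), above the 12.8 CPM of SHF progenitor-like cells in that replicate, so the call does not separate expression from free RNA. The calls of Scube3 and Shh held adjusted over the list alone, and the list had a camera adjusted p of 0.356 (fry, higher in SHF progenitor-like cells, adjusted p = 0.0188). Its median of 1.37 was 0.71 with the genes at 0 UMIs placed at their bound.

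**Figure D1:**
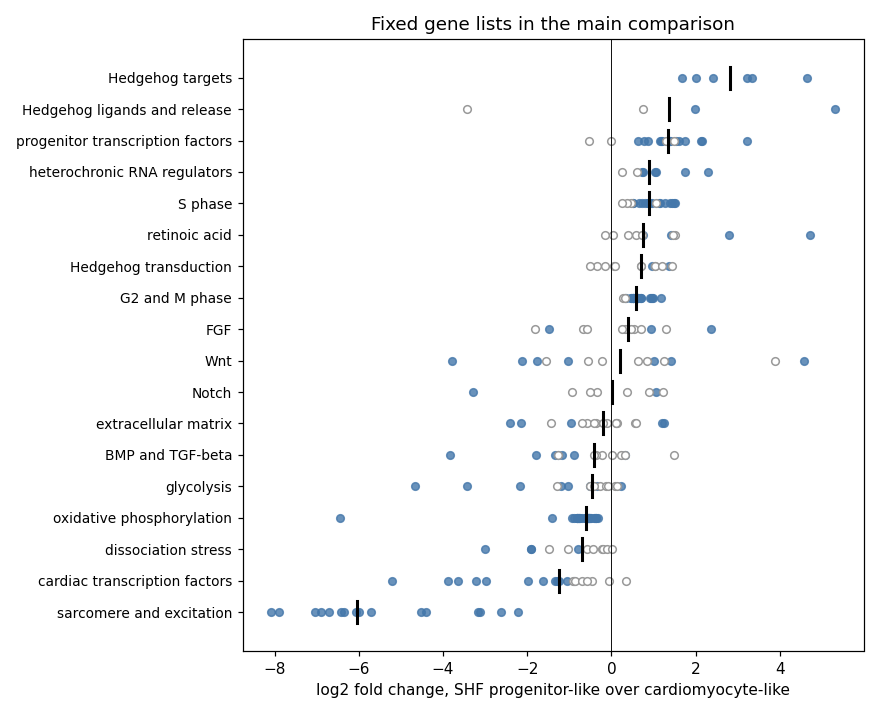
Each point is a measured gene of a fixed list, placed by its log2 fold change between SHF progenitor-like and cardiomyocyte-like cells (horizontal axis), filled where the adjusted p was under 0.05 and hollow otherwise, with a black bar at the list's median. The Hedgehog targets lay to the right of 0 (median 2.81) and the sarcomere genes to the left (median -6.04), while genes with 0 UMIs in a class, such as Shh, sit at fitted values that are no bound.

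Genes known from heterochronic control, the timing of developmental programmes, were also higher in SHF progenitor-like cells. Of 8 measured, 6 passed over all genes and 7 adjusted over the list alone. Hmga2 (chromosome 10, 120361275 to 120476469), a chromatin protein gene repressed by let-7 microRNAs, stood at 747 ± 106 against 339 ± 63.1 CPM, and Lin28b (chromosome 10, 45376620 to 45486395), an inhibitor of let-7 maturation, at 106 ± 32.1 against 20.1 ± 0.863 CPM. They were 2.08-fold and 4.89-fold higher, with adjusted p of 5.76e-11 and 1.31e-09 (edgeR quasi-likelihood, Benjamini-Hochberg). Mycn was 3.37-fold, Lin28a 2.06-fold, Igf2bp2 1.69-fold and Igf2bp1 1.65-fold higher. Igf2bp3 (290 ± 65.2 against 229 ± 58.4 CPM) and Trim71 (29.3 ± 4.29 against 18.2 ± 3.80 CPM) did not pass over all genes. The list's camera adjusted p was 6.12e-06, and adjusted p = 0.0143 with an estimated correlation.

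Progenitor transcription factors were higher in SHF progenitor-like cells for 14 of 18 measured members, with 15 higher and 1 lower adjusted over the list alone. Meis2 was 2.21-fold, Hoxb2 2.63-fold and Foxp1 1.70-fold higher, and the list's median log2 fold change was 1.34 (camera adjusted p = 2.42e-06). The cardiac transcription factors went the other way for 12 of 19, over all genes and adjusted over the list alone. Nkx2-5 stood at 371 ± 134 CPM in cardiomyocyte-like cells against 43.0 ± 20.3, and Mef2c, Tbx20 and Hopx were 7.88-fold, 12.5-fold and 37.4-fold higher there, with a list median of -1.26 for SHF progenitor-like over cardiomyocyte-like cells (camera adjusted p = 3.97e-08). All 16 measured sarcomere and excitation genes were higher in cardiomyocyte-like cells, led by Csrp3 (1037 ± 306 against 9.69 ± 9.20 CPM), Tpm1 (9.04-fold), Ttn (81.9-fold) and Nebl (23.1-fold). The median of that list was -6.04, or -5.85 with its gene at 0 UMIs placed at the bound (camera adjusted p = 6.64e-27).

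All 29 measured genes of oxidative phosphorylation were higher in cardiomyocyte-like cells, over all genes and adjusted over the list alone, with a median log2 fold change of -0.60 for SHF progenitor-like over cardiomyocyte-like (camera adjusted p = 4.91e-19). Slc25a4, the mitochondrial ADP/ATP carrier, was 2.65-fold higher, Cox5a 1.78-fold, Atp5b 1.67-fold and the muscle isoform Cox7a1 87.9-fold. Of 16 glycolysis genes, 7 were higher in cardiomyocyte-like cells, among them Pfkp (25.4-fold), Hk1 (10.8-fold), Slc2a1 (4.49-fold) and Aldoa (2.04-fold), and Pkm was 1.17-fold higher in SHF progenitor-like cells. The counts were the same adjusted over the list alone, and the list's camera adjusted p of 0.000278 became adjusted p = 0.153 with an estimated correlation.

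Cell cycle genes were higher in SHF progenitor-like cells. Of 20 S phase genes 16 passed (17 adjusted over the list alone), with Rrm2, a ribonucleotide reductase subunit, 2.80-fold, Hells 2.71-fold, Cdca7 2.63-fold and Tyms 2.21-fold higher and a list median of 0.89 (camera adjusted p = 1.05e-10). Of 22 genes of G2 and M phase 20 passed, and all 22 adjusted over the list alone, with Kif20b 2.25-fold, Bub1 1.95-fold, Cdc20 1.90-fold and the topoisomerase gene Top2a 1.54-fold higher and a list median of 0.59 (camera adjusted p = 1.78e-09).

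Signalling lists were mixed. Of 11 retinoic acid genes, 4 were higher in SHF progenitor-like cells, also adjusted over the list alone. Among these were Crabp1 (1.67-fold, but -0.02 on the log2 scale with doublets kept), the retinol receptor Stra6 (75 UMIs against 1, ratio 33.1, interval 5.77 to 1330) and Rxra (36 against 2, ratio 7.95, interval 2.05 to 68.2), with a list median of 0.74 and a camera adjusted p of 0.0213, which became 0.297 with cells thinned to 1000 UMIs. Of 15 BMP and TGF-beta genes 6 were higher in cardiomyocyte-like cells and 1 was lower, with the same counts adjusted over the list alone. Bmp2 was 14.2-fold, Bambi 3.49-fold, Tgfb2 2.28-fold and Bmp4 1.85-fold higher there (camera adjusted p = 0.0201, adjusted p = 0.0682 with an estimated correlation). Of 14 Wnt genes 3 were higher in SHF progenitor-like cells and 4 in cardiomyocyte-like cells (6 and 5 adjusted over the list alone). Wnt5a was 2.69-fold higher in the former, and Sfrp5, Wnt2 and Sfrp1 were 13.8-fold, 3.39-fold and 2.04-fold higher in the latter. For Sfrp1 the difference came from the middle of the score between the 2 classes, since its levels at the 2 ends were alike (338 ± 125 and 344 ± 61.7 CPM). Tgfb2 was also highest in the middle of that score. That list's median was 0.20, or -0.12 with its gene at 0 UMIs at the bound, its mean was 0.18, and camera gave an adjusted p of 0.976, while fry pointed towards cardiomyocyte-like cells (adjusted p = 0.0345).

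Of 12 FGF genes, Fgfr1 (1.91-fold) and Fgf9 (38 UMIs against 3, ratio 5.60, interval 1.78 to 28.3) were higher in SHF progenitor-like cells and the feedback phosphatase gene Dusp6 was 2.81-fold higher in cardiomyocyte-like cells, also adjusted over the list alone, and Etv4 (8.84 ± 2.75 against 3.29 ± 2.68 CPM) did not pass (camera adjusted p = 0.526). Of 8 Notch genes, Notch3 was 2.07-fold higher in SHF progenitor-like cells and Hey1 9.74-fold higher in cardiomyocyte-like cells, with 2 and 1 adjusted over the list alone. Notch2 (29.7 ± 7.55 against 15.1 ± 10.3 CPM) and Hes1 (77.6 ± 16.3 against 56.7 ± 17.0 CPM) did not pass over all genes. The median of that list was 0.02 and its mean -0.19, and camera and fry differed in direction (camera adjusted p = 0.871). Of 17 extracellular matrix genes, Col3a1 (2.38-fold) and 1 other were higher in SHF progenitor-like cells and Col1a1 (5.31-fold), Col2a1 (4.45-fold) and Lamb1 (1.94-fold) in cardiomyocyte-like cells, with the same counts adjusted over the list alone (camera adjusted p = 0.340; fry, towards cardiomyocyte-like cells, adjusted p = 0.00803). Immediate-early genes that dissociation can induce were higher in cardiomyocyte-like cells for 4 of 12 members, also adjusted over the list alone: Atf3 (7.99-fold), Ier3 (3.77-fold), Zfp36 (3.75-fold) and Jun (1.73-fold), with a camera adjusted p of 0.0372 and adjusted p = 0.167 with an estimated correlation. The calls of the Hedgehog target, heterochronic, progenitor and cardiac transcription factor, sarcomere, oxidative phosphorylation, S phase, G2 and M phase, and retinoic acid lists held with an estimated correlation.

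The fit used the library as a block. With no replicate block 233 genes were higher in SHF progenitor-like cells and 433 in cardiomyocyte-like cells, a split of 35% to the former against 49.2% with the block, and with each cell thinned to 1000 UMIs the counts were 237 and 366, a split of 39.3%. With no replicate block the calls of Shh, Lin28a, Kif20b, Cdc20, Top2a, Sfrp1, Crabp1, Bmp4, Fgfr1, Fgf9, Notch3, Lamb1, Jun and Ier3 ended, and with the DESeq2 Wald test those of Trdn, Hspb3, Foxl1, Rxra, Shh, Sfrp1, Crabp1, Bmp4, Fgf9, Notch3 and Ier3. With cells thinned to 1000 UMIs those of Foxc2, Smo, Scube3, Shh, Lin28a, Wnt5a, Crabp1, Fgfr1, Lamb1, Atf3 and Jun ended, with the counts split into a clustering and a testing share those of Smo, Shh, Crabp1, Fgfr1, Notch3 and Atf3, and with at least 800 genes per cell those of Shh, Dusp6, Zfp36 and Ier3. Under the other alternatives with a test, the calls that ended were those of Shh (another random share of the genes, doublets kept, joint scaling), Crabp1 (no mitochondrial filter, joint scaling, and doublets kept, where its sign also changed), Fgf9 (both other resolutions, doublets kept, joint scaling, no mitochondrial filter) and Notch3 (DESeq2 size factors, no low-count filter, resolution 1.6, another random share of the genes). All 77 called genes that the rule for named genes chose with over 3 UMIs in the lower class kept their direction in each library alone. The rule itself required this of those that were not list members. In 1 of the libraries alone, 17 of the 77 folds moved by more than 1.5 times towards no difference. These were, as log2 fold changes, Ypel1 (1.40), Foxc2 (0.99), Col2a1 (-1.16), Ier3 (-1.16), Atf3 (-1.70), Cox7a1 (-5.29) and Acta1 (-6.45) without replicate 2, and Barx1 (2.78), Sparcl1 (2.44), Hey1 (-2.69), Sfrp5 (-3.07), Bmp2 (-3.12), Nebl (-3.59), Hopx (-3.74), Ppp1r14c (-5.98), Csrp3 (-6.19) and Hspb1 (-6.36) without replicate 1.

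The second comparison asked which classes carried the Hedgehog ligand and which the response. Of the ligand genes Shh, Ihh and Dhh, only Shh was among the 4 genes of ligands and release with enough counts to be tested. Shh was highest in foregut endoderm-like cells, at 219 ± 47.4 CPM against a mean of 6.42 ± 0.390 CPM over the other 11 classes (log2 fold change 6.92 ± 0.27, adjusted p = 1.18e-26, edgeR quasi-likelihood with Benjamini-Hochberg). Among the 12 named classes, Foxf1, Gli1, Hhip, Foxl1 and Ptch1 were highest in SHF progenitor-like cells, while Gli1 (81.3 CPM) and Ptch1 (139 CPM) had higher means in unnamed cluster 10, Ptch1 only through replicate 2 (194 against 79.6 CPM), since in replicate 1 it was lower there (83.7 against 108 CPM). Against the mean of the other classes, their log2 fold changes were 5.28 ± 0.22 (Foxf1), 4.94 ± 0.52 (Foxl1), 3.73 ± 0.30 (Gli1), 3.70 ± 0.27 (Hhip) and 1.86 ± 0.16 (Ptch1), each with an adjusted p of 1.36e-10 or smaller (edgeR quasi-likelihood), and higher in both libraries. Mean levels were 42.1 against 6.32 CPM for Gli1 and 93.6 against 26.2 CPM for Ptch1. Foxc2 passed the same test, since the contrast averages log levels, but its 17.9 ± 4.28 CPM was no higher than the mean of 18.7 ± 1.40 CPM in the others, and it was highest in paraxial mesoderm-like (87.1 ± 5.30) and endocardial or endothelial-like cells (81.2 ± 22.9). All 6 targets passed adjusted over the list alone as well. With cells thinned to 1000 UMIs, 3 targets (Foxf1, Ptch1 and Foxc2) had enough counts to be tested, and all 3 passed.

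Foregut endoderm-like cells also had raised Ptch1 (45.8 ± 0.109 CPM) with 0 UMIs of Foxf1 and 5.56 CPM of Gli1. In surface ectoderm-like cells, a class that of the alternatives only the one with doublets kept also named, Scube3 (80.4 ± 13.8 CPM), Lrp2 (70.4 ± 2.50 CPM) and Gas1 (251 ± 83.8 CPM) were higher than in the other classes, with log2 fold changes of 3.50 ± 0.31, 5.33 ± 0.45 and 2.41 ± 0.18. Scube2, which helps release lipid-bound ligand, was higher in neural tube-like cells (26.8 ± 9.06 CPM, adjusted p = 6.41e-08, edgeR quasi-likelihood). Gas1, a coreceptor gene, was also raised in pharyngeal or limb mesenchyme-like (175 ± 23.4 CPM) and epicardial-like cells (124 ± 8.96 CPM). Calls were not confined to these genes and classes. Epicardial-like cells had 2 of the 6 measured targets higher than the mean of the other classes and 0 lower. Hepatoblast-like cells had 2 of the 4 measured genes of ligands and release higher and 1 lower.

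**Figure D2:**
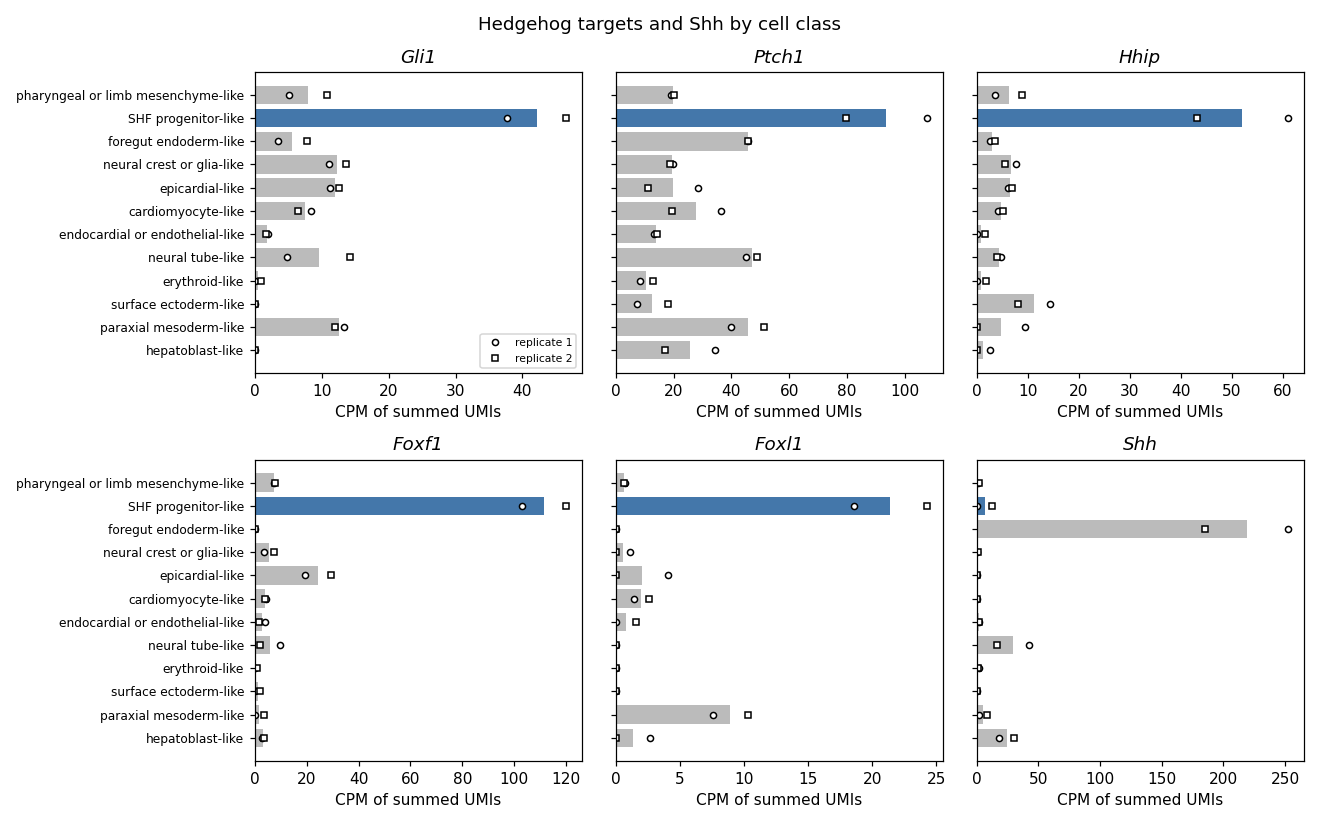
Bars give the mean CPM of summed UMIs over the 2 libraries (horizontal axes, from 0) for 6 genes in the 12 named classes (rows), with the SHF progenitor-like class in blue and a circle or square for each replicate. Among these classes Gli1, Ptch1, Hhip, Foxf1 and Foxl1 were highest in the SHF progenitor-like class and Shh in the foregut endoderm-like class.

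Each class was then set against the mean of the others on held-out genes. Cardiomyocyte-like cells had 1030 genes higher, led by Cox6a2, Trim55, Casq1 and Trdn, and endocardial or endothelial-like cells 919, led by Ctla2a, Clec14a, Cldn5 and Gja4. SHF progenitor-like cells had 714, led by Cxcl13, Nkx6-1, Fendrr and Barx1, and epicardial-like cells 703, led by Shisa3, Itga4, Barx1 and Gucy1a3. Foregut endoderm-like cells had 818 (Nepn, Cldn4, Krt7, Ap1m2), neural crest or glia-like cells 740 (Phactr1, Ret, Camk2b, Tfap2a), surface ectoderm-like cells 583 (Sostdc1, Sfn, Cxcl14, Ppl) and neural tube-like cells 541 (Hes5, Glra1, Pou3f2, Btbd17). Pharyngeal or limb mesenchyme-like cells had 513 (Lix1, Col26a1, Sema3a, Pcolce), hepatoblast-like cells 502 (Serpinf2, Paqr9, Bhmt, Apom), paraxial mesoderm-like cells 412 (Bgn, Cped1, Fst, Col9a1) and erythroid-like cells 1462 (Aqp3, Slc30a10, Ncf4, Hbq1b). Barx1 stood at 94.9 ± 25.5 CPM in SHF progenitor-like and 73.4 ± 8.62 CPM in epicardial-like cells, and Cldn5, a tight junction gene of endothelium, at 245 ± 59.9 CPM in its class. Nepn varied between libraries in foregut endoderm-like cells (356 ± 422 CPM).

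The last comparison placed SHF progenitor-like and cardiomyocyte-like cells on a score running between the 2 classes and asked which held-out genes followed it. Sarcomere and cardiac transcription factor genes rose along it while Hedgehog targets and heterochronic genes fell. Ttn rose by 2.31 ± 0.15 (SE) on the log2 scale per bin and Nkx2-5 by 1.35 ± 0.10, and Foxf1 fell by 2.40 ± 0.18, Hhip by 1.23 ± 0.19, Gli1 and Lin28b each by 1.08, and Ptch1 by 0.60 ± 0.11. Over 4 bins and 3228 genes, 515 rose and 463 fell (edgeR quasi-likelihood, adjusted p under 0.05). The bins are ranges of a score, not cell types: bin 1 held only cells of the SHF progenitor-like cluster, and 76.6% and 74.7% of bin 2 and all of bins 3 and 4 came from the cardiomyocyte-like cluster in replicates 1 and 2. The trend therefore largely repeats the first comparison on the same cells and is not independent evidence for it.

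In the test for the middle bins, 15 genes were higher in a middle bin than at both ends. Ptn, a secreted growth factor gene (chromosome 6, 36714929 to 36810220), went from 544 ± 78.3 CPM in bin 1 to 1532 ± 250 in bin 2, 1167 ± 121 in bin 3 and 216 ± 12.1 in bin 4 (adjusted p = 1.50e-10, edgeR quasi-likelihood). The Wnt antagonist gene Sfrp1 stood at 868 ± 175 CPM in bin 3 against 338 ± 125 and 344 ± 61.7 at the ends, and Asb4 at 259 ± 26.1 against 26.2 ± 2.77 and 78.3 ± 6.75. Flrt3 (antisense to Macrod2), Tgfb2 and Col1a2 peaked in bin 2 at 298 ± 121, 386 ± 95.5 and 231 ± 8.21 CPM, and Lima1 and Actb in bin 3 at 127 ± 4.59 and 7993 ± 1567 CPM. Sfrp1, Tgfb2 and Col1a1, given above as higher in cardiomyocyte-like cells, were among the 15 genes. Tgfb2 stood at 107 ± 30.1 CPM in bin 1 and 152 ± 14.0 in bin 4. The class differences of Sfrp1 and Tgfb2 thus rest largely on the middle bins, and explanations for the rise there are weighed below. Bin 2 had the lowest median depth, 1506 and 1378 UMIs, against 2603 and 2245 in bin 1. With no replicate block 1 gene was higher in a middle bin, with 4 bins before merging 7, and with a score from cells thinned to 1000 UMIs, chosen after seeing the data, 6.

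**Figure D3:**
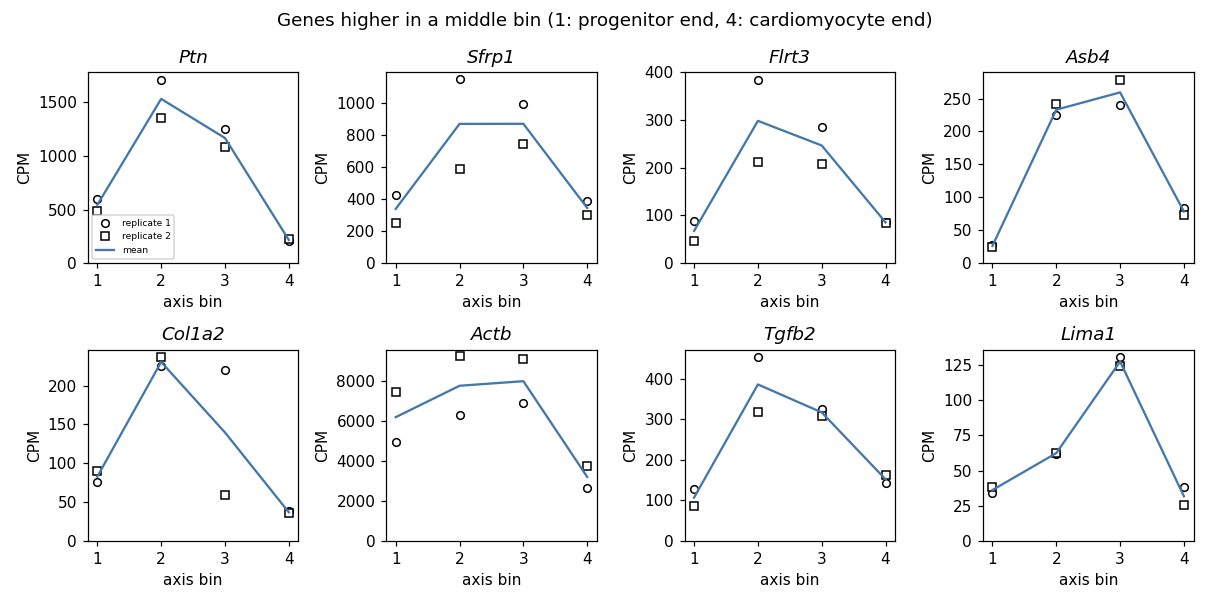
CPM of summed UMIs (vertical axes, from 0) over the 4 bins of the score between SHF progenitor-like (bin 1) and cardiomyocyte-like cells (bin 4) for 8 genes, with a circle or square for each replicate and a line through the means. Ptn peaked in bin 2 at 1532 CPM and Lima1 in bin 3 at 127 CPM, both above bins 1 and 4.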

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

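The tests of explanations for the genes higher in the middle bins were chosen after the result was seen, and so was the score from thinned cells.

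Hedgehog targets had UMIs in the 2 unnamed clusters, which entered no comparison, above the limit that a count of 0 allows. In cluster 10, which had 287 cells and was led by Kcnq1ot1 and the nuclear RNA Malat1 among others, Gli1 stood at 81.28 CPM and Ptch1 at 139.07 CPM (83.7 in replicate 1 and 194.4 in replicate 2), against means of 42.1 and 93.6 CPM in SHF progenitor-like cells, where Ptch1 was higher in replicate 1 (107.7 CPM) and lower in replicate 2 (79.59 CPM) than in the cluster. Longer genes were raised in cluster 10, with median log2 ratios from -0.77 in the shortest to 0.56 in the longest of 5 groups of genes in replicate 1 and from -0.56 to 0.57 in replicate 2. The targets' median of 0.76 in replicate 2 lay at percentile 88.81 of random sets matched on length and level and that of 1.27 in replicate 1 at percentile 99.71, so gene length cannot be told apart as the cause, since the libraries differed. Progenitor-like cells in that cluster are a candidate explanation: the median of 100 genes that mark the SHF progenitor-like class at 20 CPM or more was 1.02 and 0.79, above the upper bounds of the central 95% of matched sets (0.44 and 0.51), at percentile 100.0 in both libraries. Marking genes of other classes were not scored in cluster 10, so whether this rise is particular to progenitor genes was not tested. Of the targets, only Gli1 and Ptch1 passed the limit named above in cluster 10. Foxf1, at a mean of 112 CPM in SHF progenitor-like cells, did not pass it. That does not decide about progenitor-like cells, since Foxf1 is a short gene (121084386 to 121088144 on chromosome 8). The group of the shortest genes, with a median length of 3.0 kb, was lowered in cluster 10. No other explanation was tested.

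In cluster 1, with 2173 cells at median depths of 708 and 785 UMIs, Gli1 stood at 10.08 CPM, Ptch1 at 29.96, Hhip at 7.15, Foxf1 at 28.08, Foxf2 at 4.97, Foxl1 at 7.82 and Foxc2 at 11.89. Barcodes with 10 to 200 UMIs, taken here as mostly free RNA, carried the embryonic globin transcript Hbb-y at 14461.2 CPM in replicate 1 (117 barcodes, 8713 UMIs) and at 9478.5 CPM in replicate 2 (333 barcodes, 55494 UMIs). They also held 1 and 2 UMIs of Foxf1 (114.8 and 36.0 CPM), 0 and 6 of Ptch1 (108.1 CPM in replicate 2) and 0 and 1 each of Gli1 and Hhip (18.0 CPM in replicate 2), so these values do not separate expression in cluster 1 from free RNA.

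The genes higher in a middle bin of the score than at both ends, among them Ptn, Sfrp1 and Tgfb2, were weighed against mixtures of cells and against depth. A doublet of cells like those at the 2 ends cannot exceed both, but with the cells of the highest 10% of doublet scores removed, the 15 held-out genes highest in a middle bin of 1 library had a median smaller log2 fold change over the ends in the other library of 0.59 (SE over genes 0.19) in replicate 2 and 1.29 (SE 0.30) in replicate 1. With score and sums from cells all thinned to 1000 UMIs these medians were 1.34 (SE 0.29) and 0.85 (SE 0.26), and for the 15 genes called before thinning the median went from 1.39 (SE 0.148) to 1.25 (SE 0.224), while 6 genes passed in the thinned cells, for a reason not tested. For pharyngeal or limb mesenchyme-like cells, the share that 30 held-out genes marking that class allow in a middle bin (at most 49.6%, upper 95% counting limit) would bring a median of 16.0% and 13.4% of the rise of the 15 genes in replicates 1 and 2, although it would bring at least 25% for 6 of them and up to 81.9% for 1. Epicardial-like cells or their RNA cannot be told apart as a source. For them the share allowed by 30 such genes, at most 64.5%, would bring a median of 47.3% and 72.3% of the rise. It would bring at least 25% for 11 of the 15 genes in each library. The highest values were 283.7% in replicate 1 and 338.2% in replicate 2, more than the whole rise of a gene. The 2 sets of marking genes had members in common, among them Gap43, Fn1 and Tnc, so the 2 shares are not separate. Explanations other than these were not tested.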

How the results depend on the processing

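The score from thinned cells was chosen after seeing the data, and the other alternatives were fixed beforehand. Of the values of the genes that the naming rule chose, over the alternatives with a test, 1427 kept their direction and side of the threshold, 60 lost their call, 15 gained one and 1 changed sign without a call, and of the lists' values these numbers were 270, 11, 7 and 0. Of 1618 calls between SHF progenitor-like and cardiomyocyte-like cells, 0 were called in the other direction under any alternative, 666 held with no replicate block and 1166 with the DESeq2 Wald test, and 569 of 1172 still tested held with cells thinned to 1000 UMIs, where 2885 genes were tested. With 1 library left out there was no test, and 61 genes' values without replicate 1 and 66 without replicate 2 stayed within the spread, 50 and 45 moved further, and 0 called values changed sign. For genes outside the lists the naming rule had required the same direction in both libraries. The fit of only the 2 classes compared has 1 residual degree of freedom.

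With no replicate block 233 genes were higher in SHF progenitor-like and 433 in cardiomyocyte-like cells, and the genes higher in a class numbered 417 (epicardial-like), 444 (foregut endoderm-like), 208 (neural crest or glia-like), 296 (neural tube-like), 221 (paraxial mesoderm-like), 217 (pharyngeal or limb mesenchyme-like) and 237 (SHF progenitor-like). Along the score 255 fell and 1 was higher in a middle bin with no replicate block. The DESeq2 Wald test gave 484 genes higher in SHF progenitor-like than in cardiomyocyte-like cells, and 434 for neural crest or glia-like, 319 for pharyngeal or limb mesenchyme-like and 438 for SHF progenitor-like cells against the others. Cells thinned to 1000 UMIs gave 237 and 366 genes and 3 Hedgehog targets, since only 3 targets had counts enough to be tested; calls were lost both among genes no longer tested and among genes still tested. With an estimated correlation camera called 3 lists higher in cardiomyocyte-like cells, against 6. Crabp1 had a log2 fold change of -0.02 with doublets kept, and the cause was not tested.

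SHF progenitor-like cells made up 17.0% of kept cells with at least 800 genes per cell, 12.1% at resolution 1.6 and 12.4% with another random share of the genes. Cardiomyocyte-like cells made up 5.80%, 5.18% and 5.67% under these settings and 4.04% with the counts split into a clustering and a testing share. With the settings fixed beforehand these 2 shares were 9.92% to 11.7% and 4.48% to 4.83% by library, and with genes scaled over both libraries together the former was 14.3% in replicate 1 and 8.31% in replicate 2. The cells in a class changed too. Of 921 SHF progenitor-like cells, 640 kept that class with another random share of the genes, 678 with split counts, and 777 and 834 at resolutions 0.6 and 1.6. With at least 800 genes per cell 563 of 788 kept it. Of 402 cardiomyocyte-like cells, 386 kept theirs with another random share of the genes and 328 with split counts. Genes higher in a middle bin numbered 7 with 4 bins and 9 with 8 bins, and with the score from cells thinned to 1000 UMIs 188 genes rose, 145 fell and 6 were higher in a middle bin. The cause was not tested, and the counts of the thinned fits were not separated from their smaller number of genes and UMIs.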

Other observations

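The list tests below, each class against the mean of the others, were not among the planned comparisons.

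Signalling and matrix lists differed between classes beyond the SHF progenitor-like and cardiomyocyte-like cells. Of 15 BMP and TGF-beta genes, 13 were higher in epicardial-like cells than in the mean of the other classes (list median log2 fold change 1.42, camera adjusted p = 3.13e-12, adjusted p = 0.000727 with an estimated correlation). Of 17 extracellular matrix genes 12 were higher there and 2 lower (median 1.03, camera adjusted p = 1.84e-09). In paraxial mesoderm-like cells, 12 of the 17 were higher (median 1.55, camera adjusted p = 3.67e-19), and in neural tube-like cells 13 were lower (median -1.49, camera adjusted p = 1.54e-07). Of 12 FGF genes 11 were higher in foregut endoderm-like cells (median 1.48, camera adjusted p = 3.27e-09, adjusted p = 0.00120 with an estimated correlation).

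Higher heterochronic regulators were not confined to SHF progenitor-like cells. Of the 8 genes, 7 were higher than in the mean of the other classes in SHF progenitor-like (median 0.64), foregut endoderm-like (0.59) and neural crest or glia-like cells (0.77), and all 8 were lower in erythroid-like cells (-2.94), with camera adjusted p of 0.0149, 0.0188, 0.0172 and 0.0284 with an estimated correlation. Cardiac transcription factors were higher than in the other classes not only in cardiomyocyte-like cells (17 of 19, median 3.21) but also in SHF progenitor-like (12, median 1.64), epicardial-like (11, median 2.05) and pharyngeal or limb mesenchyme-like cells (10, median 0.95), each with a camera adjusted p of 0.00278 or smaller with an estimated correlation. S phase genes were lower in cardiomyocyte-like cells for 18 of 20 (median -0.90, adjusted p = 0.0294 with an estimated correlation). Apart from SHF progenitor-like against cardiomyocyte-like cells in the first comparison, whether these values differ between the classes named was not tested.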
